A study of Mus musculus with 6 samples.

How the data were processed

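Tongues of 6 mice were profiled by droplet single-cell RNA sequencing, 3 given 4-nitroquinoline 1-oxide (4-NQO), a carcinogen that forms DNA adducts, at 100 µg/mL in the drinking water for 16 weeks, and 3 given the vehicle alone for the same time. Each mouse gave one library, and the libraries are named Control 1 to 3 and 4-NQO 1 to 3 by group and replicate number. Per the labels, whole tongues were digested with trypsin and collagenase for 30 minutes, passed through a 70 µm strainer and loaded at about 10000 cells per library without a sort, with viability above 90%. The deposited files hold raw UMI counts per gene and cell barcode, with no normalization, as filtered matrices of 32285 genes. The submitters' processing notes name Cell Ranger, the mm10 genome and Seurat 5.0, without saying what Seurat was used for. The deposited counts were whole numbers, and the gene table was identical in all 6 libraries.

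Barcodes with at least 300 genes, at least 500 UMIs and at most 20% of UMIs from mitochondrial genes were kept, which left 23615 of 26724. Scrublet in scanpy 1.11.5 was run per library with an expected doublet rate of 0.06. It called 43 cells, 0.18% of those passing, so doublets were left largely in place, and an alternative without the 6% of cells with the highest doublet scores in each library was added. Counts of the 23572 cells kept were scaled to a fixed total per cell and log-transformed. They were reduced to 2000 variable genes and 30 principal components. Leiden clustering at resolution 1 on 15 neighbours (leidenalg 0.10.2, Python 3.11.15, seed 1) gave 36 clusters, with no batch integration. A cluster took the name of one of 20 cell classes by fixed marker genes, with the suffix -like because no cell was sorted. At least 3 markers of the class had to be detected in 10% or more of its cells, and a cluster whose 10 most specific genes held more markers of another class stayed unnamed. So did a shallow cluster, with a median depth below 1/3 of that of the library, that had no marker of the class among those 10 genes. By this rule 31 clusters were named and 5 kept their number, with 1536 cells.

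UMI counts were summed per library and class, so that mice and not cells were the replicates. A library entered with at least 20 cells of the class, and a class was tested with at least 2 such libraries per group. Genes were filtered by filterByExpr, scaled by TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 fold changes are 4-NQO over Control, with a standard error taken from the fold change and its F statistic. CPM are TMM-scaled counts per 1e6 with the SD over libraries. The same fit was run on all cells summed. A gene was also counted as separated when all libraries of one group lay above all of the other, which chance gives for 10% of genes with 3 against 3. Gene positions come from the GENCODE mouse annotation M21.

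Gene lists were tested with camera (limma) at a preset correlation of 0.01, each in the classes it was written for and with at least 5 tested members, adjusted over 133 pairs of a list and a class. The 27 lists were 9 run in every class (proliferation, p53 response, NRF2 antioxidant, hypoxia and glycolysis, interferon response, MHC class I presentation, MHC class II presentation, dissociation stress, chemokines and cytokines) and lists for single classes. Those for epithelial-like cells were basal keratinocyte, keratinocyte differentiation, wound and stress keratinocyte, and epithelial-mesenchymal and invasion. Those for stroma were myofibroblast and tumour fibroblast, inflammatory fibroblast, steady-state fibroblast, fibrillar and associated collagens, angiogenic endothelium, and activated endothelium. Those for immune cells were tumour-associated macrophage, tissue-resident macrophage, inflammatory monocyte and macrophage, activated neutrophil, cytotoxic T cell, T-cell exhaustion, regulatory T cell, and type 17 and gamma-delta T cell. Members called were counted over all genes tested and adjusted over the list alone. Shares of cells per library were compared by a two-sided exact permutation test of the difference of means, whose smallest p with 3 against 3 is 0.1.

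Genes were named by a rule: called, separated, a mean of at least 20 CPM in the higher group, and a level in the class of at least 1/5 of the highest in any other class, as a guard against free RNA. Of these the 10 largest rises and falls were taken in epithelial-like and fibroblast-like cells and 5 in other classes, and in addition up to 2 members of each list in each direction. Other genes named below are marked as chosen after their values were seen.

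The groups, tests, marker and gene lists, naming rule and most alternatives were fixed before the data were examined. These alternatives were DESeq2 1.42.0, its median-of-ratios scaling in edgeR, no filter on low counts, a minimum fold of 1.5, sums thinned to the smallest, doublets kept, at most 10% mitochondrial UMIs, resolution 2, all deposited barcodes and only genes not far higher in another class. They further were a replicate block, camera with an estimated correlation, fry, edgeR on numbers of cells, and leaving out each library in turn. Chosen after seeing the data were the removal of the highest doublet scores, each cluster fitted alone, shallow clusters left out (median depth below 1/3 of that of the library), and a technical batch as a term in the model. That batch parts the libraries at the median share of UMIs on 2 transcripts that overlap ribosomal RNA, AY036118 and Lars2. The pipeline was tested on simulated data before use. With a planted 2-fold change, edgeR recovered 60.6% of genes in epithelial-like, 38.8% in fibroblast-like, 66.2% in macrophage-like, 55.6% in neutrophil-like and 65.6% in T-like sums. With a planted 4-fold change it was 85.7%, 84.1%, 97%, 93.8% and 92.3%. The simulated counts were independent between genes and held 200 changed genes, so recovery in the real data may be lower.

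Total UMIs in units of 1e6 were 49.1, 34.3 and 54.5 in Control 1 to 3 and 42.3, 44.9 and 51.4 in 4-NQO 1 to 3. In the same units, sums per library ranged from 13.9 to 26.4 in epithelial-like, 2.45 to 5.19 in fibroblast-like, 4.03 to 8.37 in macrophage-like, 1.40 to 8.31 in neutrophil-like and 2.14 to 3.86 in T-like cells. The median standard error of a log2 fold change was 0.17, 0.20, 0.15, 0.22 and 0.18 in these classes. Mural-like, mast-like, plasma-like, erythroid-like and Schwann-like cells and cluster 31 had too few cells per library and were compared by share only. Barcodes left out in Control 1 included 1476 with over 50% of UMIs from haemoglobin genes, against 54 to 329 in the other libraries.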

Results

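Single-cell RNA sequencing of whole tongue was used to ask how epithelial, stromal and immune cells differ after 16 weeks of 4-NQO, a chemical model of oral squamous cell carcinoma, relative to vehicle. The labels assign 3 mice to each group and name the treated group 4NQO_OSCC, with OSCC for oral squamous cell carcinoma. They give no histology, so beyond this name nothing shows whether each tongue carried a tumour. After filtering, 4087, 2772 and 5305 cells remained in Control 1 to 3 and 3725, 3605 and 4078 in 4-NQO 1 to 3, with a median of 5086, 5920 and 4757 and of 4231, 5486 and 4463 UMIs per cell. All 6 libraries had Xist between 789 and 1009 CPM and Y-linked genes at 0.13 CPM or less, the pattern of female mice.

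The first comparison was of cell composition. Neutrophil-like and macrophage-like cells were the most abundant classes in both groups, followed by epithelial-like and T-like cells. Epithelial-like cells made up 14.6 ± 2.66% of cells in controls and 18.3 ± 0.74% after 4-NQO (SD, n = 3 each), fibroblast-like cells 4.05 ± 1.04% and 5.55 ± 2.05%, and T-like cells 12.5 ± 3.17% and 9.68 ± 2.74%. Neutrophil-like cells, at 23.9 ± 11.2% and 27.1 ± 10.9%, and macrophage-like cells, at 27.0 ± 3.14% and 24.2 ± 6.34%, varied more between mice of one group than between groups. No class passed the two-sided exact permutation test. Its exact p was 0.1, the smallest that 3 against 3 allow, for blood endothelial-like cells (0.59 ± 0.07% and 0.84 ± 0.21%) and erythroid-like cells (0.92 ± 1.04%, with 2.13% in Control 1 against 0.36% and 0.28% in Control 2 and 3, and 0.12 ± 0.12%), 0.2 for epithelial-like, T-like and plasma-like cells, and at least 0.3 for the others. The lowest adjusted p over the 20 classes was 0.67. With edgeR on numbers of cells, run for 14 of the classes and not for erythroid-like, plasma-like, mast-like, mural-like or Schwann-like cells or cluster 31, 0 were called, with a lowest unadjusted p of 0.252. Enzymatic digestion without a sort can itself set such shares.

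**Figure D1:**
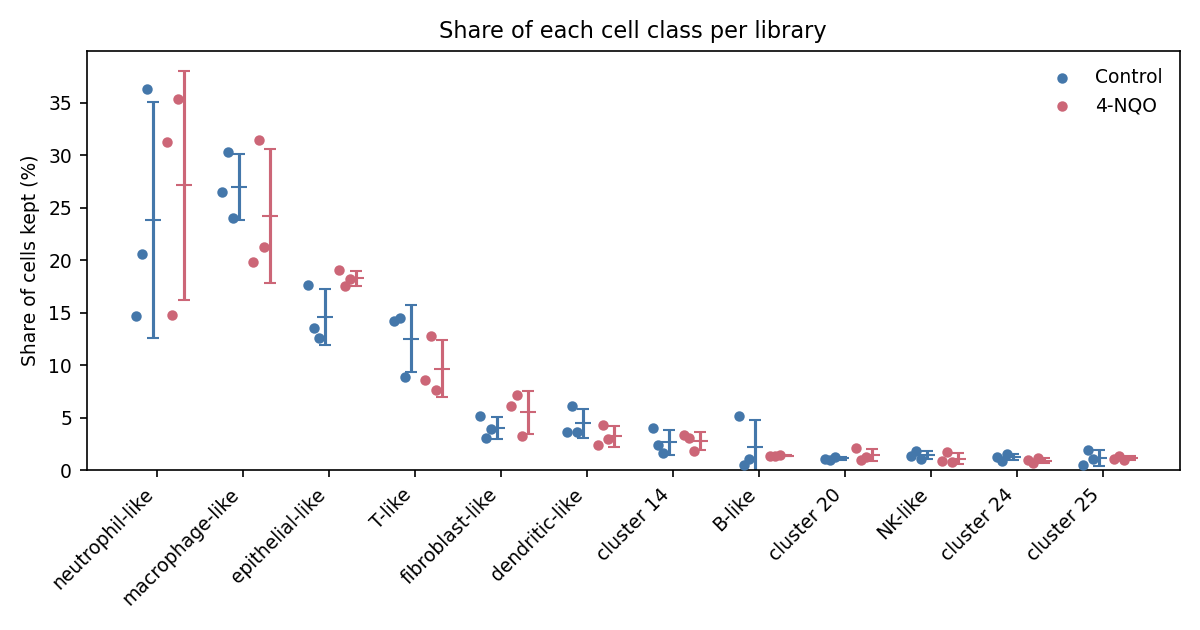
Share of the cells kept (%) in the 12 most abundant cell classes for each library, Control in blue and 4-NQO in red; dots are libraries and bars the mean ± SD (n = 3 each). The epithelial-like share had an SD of 0.74 among the 4-NQO libraries and 2.66 among controls, and the neutrophil-like share had SDs of 10.9 and 11.2.

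Across cell classes, 3 genes were called in more than 1 class, and no other gene was. Fkbp5, which encodes an immunophilin co-chaperone of steroid receptors and is induced by glucocorticoids, rose in macrophage-like, neutrophil-like, T-like and B-like cells, 7.23-fold in the first of these. Ccnd3, which encodes the G1 cyclin D3, rose in neutrophil-like and T-like cells. Smyd3, which encodes a lysine methyltransferase, fell in neutrophil-like and T-like cells and in cluster 14, a lymphoid cluster with Themis, Cd8a, Gzma and Ccl5 among its most specific genes. Each of these calls was separated, in the direction stated in all 3 mice of a group.

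In macrophage-like cells Fkbp5 went from 22.9 ± 1.06 to 166 ± 50.8 CPM (log2 fold change 2.85 ± 0.24 SE, adjusted p = 0.0451). In neutrophil-like cells Fkbp5 went from 36.8 ± 8.37 to 120.0 ± 15.1 CPM, Ccnd3 from 343 ± 40.2 to 1105 ± 178 CPM and Smyd3 from 155 ± 18.03 to 53.7 ± 7.95 CPM. The log2 fold changes were 1.74 ± 0.18, 1.69 ± 0.16 and -1.54 ± 0.16, with an adjusted p of 0.00103 for each. In T-like cells Smyd3 fell from 1013 ± 87.8 to 405 ± 29.0 CPM (-1.32 ± 0.12, adjusted p = 0.00141), Fkbp5 rose from 95.8 ± 17.4 to 211 ± 17.2 CPM (1.14 ± 0.13, adjusted p = 0.00685) and Ccnd3 from 685 ± 67.1 to 1266 ± 122 CPM (0.89 ± 0.13, adjusted p = 0.0458). Smyd3 in neutrophil-like cells lay at 8.9% of its level in cluster 14 and so outside the naming rule, and it was named after its values were seen. T-cell marker genes lay at a median of 0.6% of their T-like level in neutrophil-like cells, against 14.65% for Smyd3. Fkbp5 (ENSMUSG00000024222) and Ccnd3 (ENSMUSG00000034165) both lie on chromosome 17, from 28399094 to 28517527 and from 47505051 to 47599691, and Smyd3 (ENSMUSG00000055067) on chromosome 1 from 178951960 to 179518041. In fibroblast-like cells, where 0 genes were called, Fkbp5 had a log2 fold change of 1.37 ± 0.21 and Smyd3 of -1.004 ± 0.16, with an adjusted p of 0.628 for each and no overlap of the groups. The macrophage-like call of Fkbp5 was lost without Control 1, 2 or 3 (adjusted p = 0.267, 0.431 and 0.7) and without 4-NQO 1 or 2 (adjusted p = 0.148 and 0.136). Its log2 fold change over 19 alternatives ranged from 2.71 to 3.09 and its adjusted p from 2.19e-33 to 0.7.

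**Figure D2:**
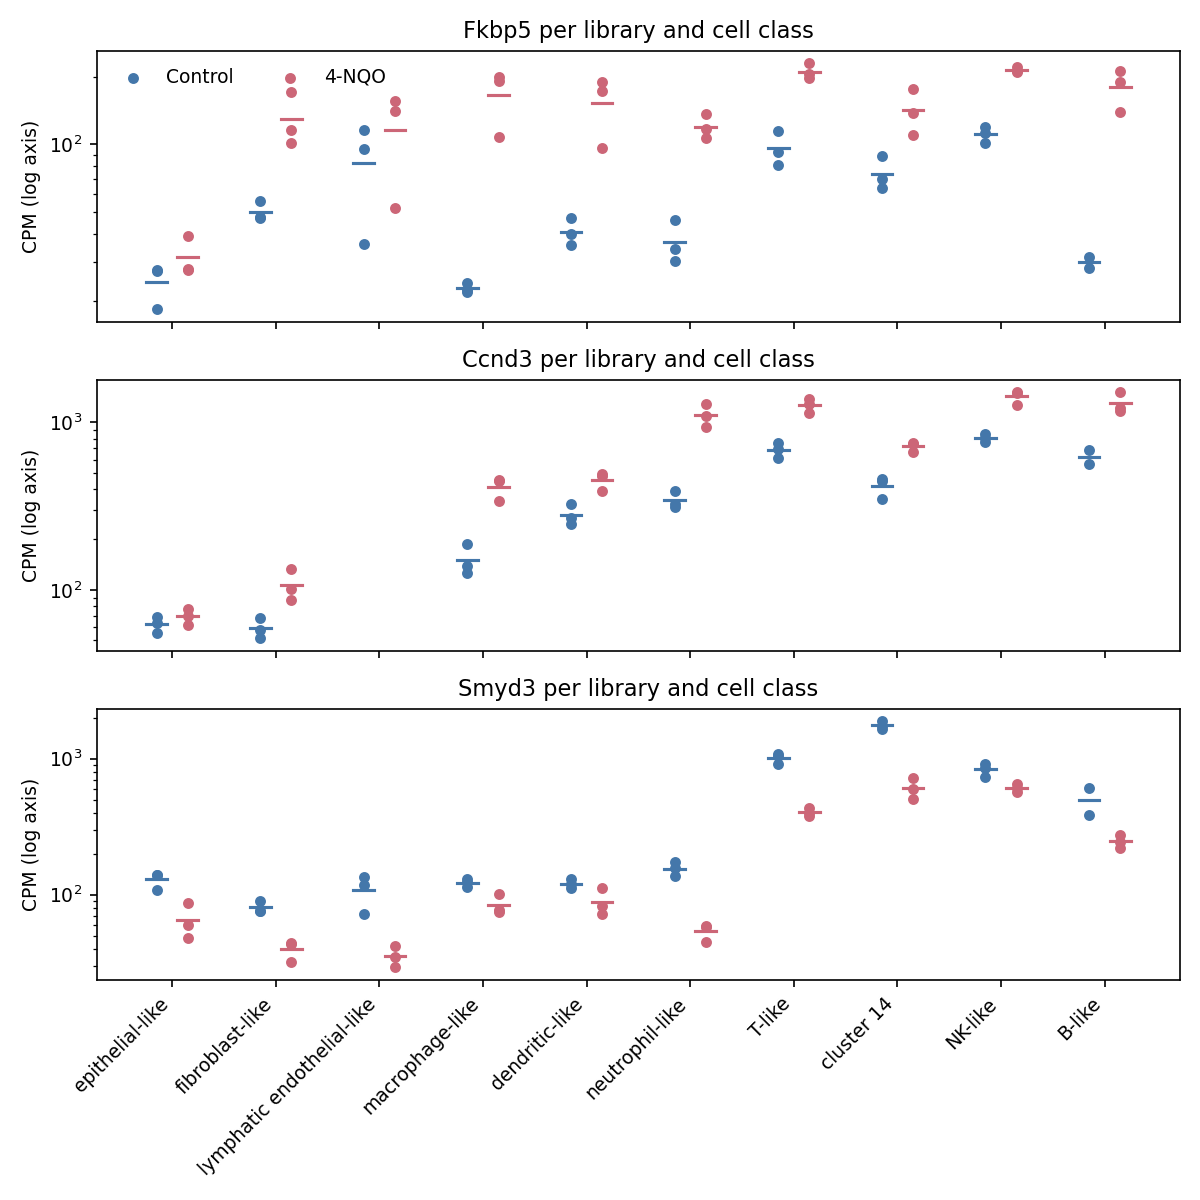
CPM per library (log axis) of Fkbp5, Ccnd3 and Smyd3 in 10 cell classes, Control in blue and 4-NQO in red; dots are libraries with at least 20 cells of the class and lines the group means. In neutrophil-like cells the 4-NQO means were 120.0, 1105 and 53.7 CPM against 36.8, 343 and 155 CPM in controls. Ccnd3 was not tested in lymphatic endothelial-like cells.

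The epithelial comparison asked which programmes differ in the cells that 4-NQO transforms. Interferon-induced genes rose as a list in epithelial-like cells, with all 23 measured members higher and a median log2 fold change of 0.46. The call was lost at an adjusted p = 0.624 with an estimated correlation. Among the members, Cxcl10, a chemokine that attracts activated T cells, was at 61.6 ± 14.01 CPM in controls and 122 ± 18.2 CPM after 4-NQO (0.98 ± 0.19), and the related Cxcl9 at 176 ± 33.1 and 234 ± 19.2 CPM. Genes of hypoxia and glycolysis fell as a list, with 17 of 19 members lower and a median of -0.30, a call lost at an adjusted p = 0.534 with an estimated correlation. Pdk1, which holds pyruvate back from the mitochondria, was at 46.3 ± 4.40 and 32.2 ± 3.49 CPM (-0.53 ± 0.12) and Bnip3, a mitophagy receptor, at 149 ± 25.8 and 104 ± 5.37 CPM (-0.53 ± 0.14). MHC class I presentation rose as a list with 13 of 13 members higher (median 0.24), lost at an adjusted p = 0.68 with an estimated correlation, among them its transactivator Nlrc5 at 79.8 ± 7.33 and 110 ± 23.03 CPM. Basal keratinocyte genes rose with 12 of 13 members higher (median 0.13), lost at an adjusted p = 0.706 with an estimated correlation, among them the hemidesmosome integrin Itgb4 at 480.2 ± 72.3 and 584 ± 77.2 CPM.

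The adjusted p was 8.53e-17 for the interferon response, 4.45e-16 for hypoxia and glycolysis, 6.35e-05 for MHC class I presentation and 0.035 for the basal keratinocyte list at the preset correlation, and with an estimated correlation none passed. Of the members, 0 were called over all genes. Adjusted over the list alone, 1 interferon member and 8 members of hypoxia and glycolysis were called, and 0 of either other list. The wound and stress keratinocyte list had 16 of 20 members lower (adjusted p = 0.0515), with the injury keratin Krt16 at 132 ± 40.0 and 78.3 ± 24.7 CPM, at 12.1% of its level in cluster 20. That cluster, with Krt13 and Sprr1a among its most specific genes, scored highest for epithelial markers but stayed unnamed. Its cells were not in the epithelial-like sums or share, and the keratinocyte lists were not run in it. Keratinocyte differentiation (10 of 18 members lower, adjusted p = 0.413) and epithelial-mesenchymal and invasion (12 of 21 higher, adjusted p = 0.131) did not pass. Nor did the p53 response (12 of 20 lower, adjusted p = 0.589), proliferation (18 of 28 higher, adjusted p = 0.281) or the NRF2 antioxidant list (adjusted p = 0.9), whose test pointed up while 12 of 19 members were lower. With the technical batch as a term, wound and stress keratinocyte (adjusted p = 0.000588) and keratinocyte differentiation (adjusted p = 0.00471) passed as lower, and epithelial-mesenchymal and invasion (adjusted p = 0.0264) and proliferation (adjusted p = 5.32e-11) as higher. The ranges over 11 alternatives were 0.000588 to 0.927, 0.00471 to 0.913, 0.000521 to 0.967 and 5.32e-11 to 0.924. The wound list also passed without Control 1, Control 2, 4-NQO 1 and 4-NQO 3 (adjusted p = 0.00871, 0.00422, 0.0154 and 0.00566), and the invasion list without 4-NQO 1 (adjusted p = 0.000521). Proliferation passed as higher without Control 2, 4-NQO 1 and 4-NQO 3 (adjusted p = 0.00259, 0.00849 and 0.00284) but as lower without Control 3 and 4-NQO 2 (adjusted p = 0.0348 and 0.0108). Cdkn1a, a p53 target that blocks the cell cycle, was at 85.0 ± 23.2 and 66.1 ± 9.33 CPM, and Mmp13, a collagenase of invading epithelium and stroma, at 1.21 ± 0.15 and 3.62 ± 1.22 CPM, 1% of its level in macrophage-like cells. At the level of single genes edgeR called 0 of 15028, and DESeq2 called 6. With edgeR 489 had an unadjusted p under 0.05, where chance gives 751. The groups were separated for 9.1% of genes, where chance gives 10%. MHC class I presentation missed the threshold with the technical batch as a term (adjusted p = 0.0597), without Control 2 (adjusted p = 0.094) and without 4-NQO 1 (adjusted p = 0.185), in a range of 2.43e-07 to 0.763 over 11 alternatives. The basal keratinocyte list missed it without Control 3 (adjusted p = 0.927) and without 4-NQO 2 (adjusted p = 0.453), in a range of 7.37e-05 to 0.927.

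**Figure D3:**
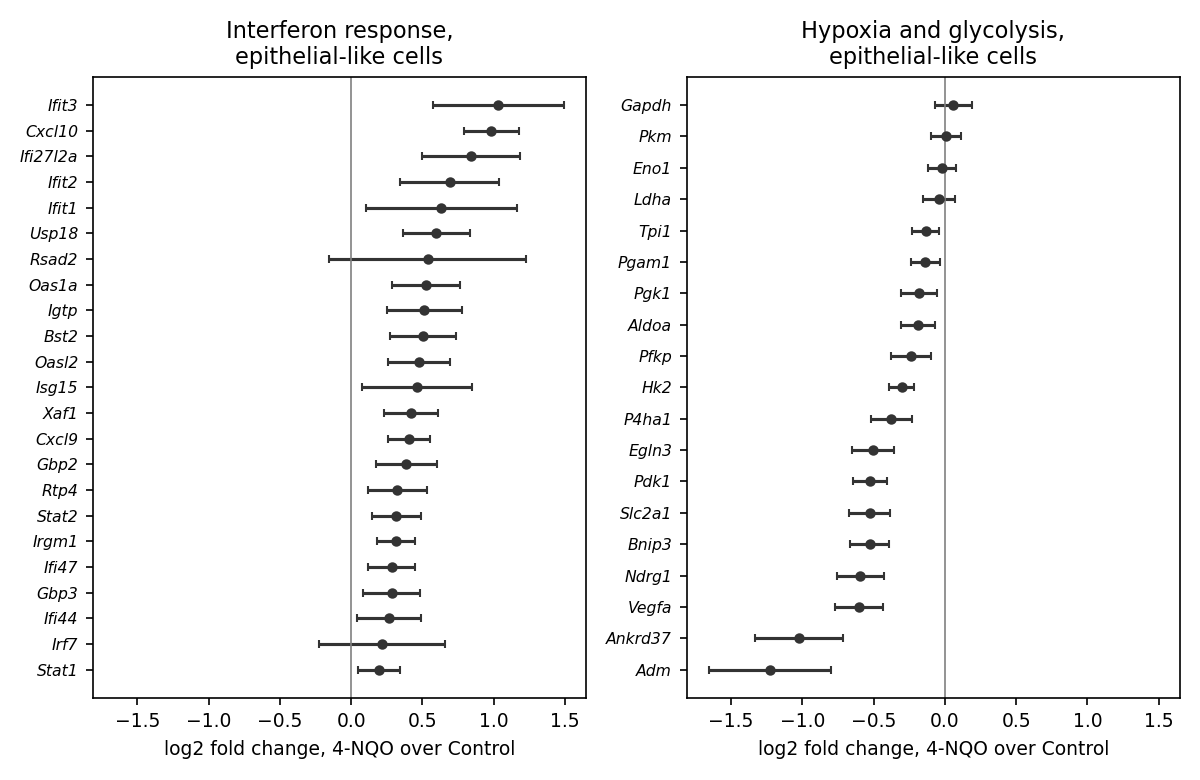
Log2 fold change (4-NQO over Control) with its standard error for each tested member of the interferon response list and the hypoxia and glycolysis list in epithelial-like cells. All 23 interferon members lay above 0, with a median of 0.46, and 17 of 19 members of hypoxia and glycolysis lay below 0, with a median of -0.30.

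Fibroblasts were compared for a shift toward the activated states of tumour stroma. The myofibroblast and tumour fibroblast list rose in fibroblast-like cells, with 16 of 20 members higher (median 0.15), as did chemokines and cytokines (10 of 14 higher, median 0.19) and the interferon response (17 of 23 higher, median 0.20). Each of these calls was lost at an adjusted p = 0.624 with an estimated correlation. Col12a1, a collagen of tissues under tension, was at 686 ± 57.0 CPM in controls and 1148 ± 315 after 4-NQO (0.74 ± 0.21) and Thbs1, a matricellular activator of TGF-beta, at 619.7 ± 116 and 930 ± 170 CPM. Fap, a protease that marks tumour fibroblasts, was at 243 ± 35.5 and 185 ± 17.99 CPM (-0.39 ± 0.15). The neutrophil chemoattractant Cxcl2 was at 16.1 ± 5.19 and 37.6 ± 16.4 CPM, 0.4% of its level in neutrophil-like cells. The neutrophil marker Il1r2, named after its values were seen, was at 20.6 and 39.2 CPM in fibroblast-like cells, with the other markers not given here. Whether free RNA from neutrophils enters the chemokine list was not tested. MHC class II presentation fell as a list, with 6 of 7 members lower (median -0.66), lost at an adjusted p = 0.624 with an estimated correlation. Its invariant chain Cd74 was at 80.8 ± 31.2 and 40.6 ± 22.1 CPM, 0.7% of its level in dendritic-like cells.

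The adjusted p was 0.00769 for the myofibroblast, 0.035 for the chemokine, 0.000293 for the interferon and 0.000142 for the MHC class II list at the preset correlation, and with an estimated correlation none passed. Hypoxia and glycolysis had 18 of 19 members lower (adjusted p = 0.0421, and adjusted p = 0.796 with an estimated correlation). Its direction turned upward with the technical batch as a term (adjusted p = 0.666), without Control 1 (adjusted p = 0.584) and without 4-NQO 1 (adjusted p = 0.764), and it missed the threshold without 4-NQO 3 (adjusted p = 0.2), in a range of 1.71e-08 to 0.907. Of the members of these lists 0 were called over all genes, and 0 adjusted over the list alone. Steady-state fibroblast genes (8 of 13 lower, adjusted p = 0.264), inflammatory fibroblast genes (adjusted p = 0.754; 10 of 18 higher, while the test pointed down) and fibrillar and associated collagens (adjusted p = 0.841; 7 of 12 lower, while the test pointed up) did not pass. The steady-state list passed as lower without Control 2 and 4-NQO 1 (adjusted p = 0.0106 and 0.0302, range 0.0106 to 0.913). The collagen Col1a2 was at 11360 ± 667 and 12510 ± 355 CPM. With edgeR 0 of 11971 genes were called and 373 had an unadjusted p under 0.05, where chance gives 599. DESeq2 called 6. Zbtb16, a zinc finger repressor that glucocorticoids induce, had the smallest p and was named after its values were seen, at 18.1 ± 7.08 and 179 ± 52.4 CPM (3.30 ± 0.34, adjusted p = 0.143, separated). In cluster 18, 1 of the fibroblast-like clusters, fitted alone, it was called with Edn1 and Fkbp5. It was also called as higher in the macrophage-like cluster 6 fitted alone, with Ccnd3, Fkbp5 and Glis3. Over 18 alternatives the adjusted p of Zbtb16 in fibroblast-like cells ranged from 2.72e-19 to 1. The myofibroblast list missed the threshold without Control 3 (adjusted p = 0.79) and without 4-NQO 3 (adjusted p = 0.235), and the chemokine list without Control 1, Control 2, 4-NQO 2 and 4-NQO 3 (adjusted p = 0.0689, 0.0686, 0.173 and 0.126), in ranges of 0.000413 to 0.79 and 0.00261 to 0.763.

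Macrophage-like cells were compared for tumour-associated and inflammatory programmes. Apart from Fkbp5, only lists passed in the fit as reported. Dissociation stress genes fell, with 14 of 19 members lower (median -0.19), hypoxia and glycolysis fell with 13 of 19 lower (median -0.02), and the interferon response rose with 20 of 23 higher (median 0.09). The first 2 calls were lost at an adjusted p = 0.624 each with an estimated correlation, and the last at an adjusted p = 0.796 with an estimated correlation. The immediate early gene Egr1 was at 266 ± 34.6 CPM in controls and 182 ± 32.6 after 4-NQO and Atf3, a stress-induced transcription factor, at 401 ± 40.3 and 319.6 ± 26.8 CPM. The glucose transporter gene Slc2a1 was at 108 ± 10.4 and 84.2 ± 3.67 CPM, and the vasodilator peptide gene Adm at 8.50 ± 2.70 and 2.43 ± 0.91 CPM.

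The adjusted p was 0.000385 for dissociation stress and 0.0015 for hypoxia and glycolysis and 0.0479 for the interferon response at the preset correlation, and with an estimated correlation none passed. Adjusted over the list alone, 2 members of hypoxia and glycolysis were called and 0 of the other lists. Tumour-associated macrophage genes had 13 of 17 members lower (adjusted p = 0.5), among them Vegfa at 74.1 ± 13.9 and 59.9 ± 7.14 CPM. Tissue-resident macrophage genes had 9 of 11 higher (adjusted p = 0.0706), among them the scavenger receptor gene Cd163 at 65.2 ± 24.4 and 131 ± 109 CPM (log2 fold change 0.20, without 4-NQO 2, to 1.48 over 19 alternatives), and inflammatory monocyte and macrophage genes had 10 of 14 lower (adjusted p = 0.0706), among them the nitric oxide synthase gene Nos2 at 14.6 ± 3.06 and 7.35 ± 0.42 CPM. The tissue-resident list passed with the technical batch as a term (adjusted p = 7.33e-05, range 7.33e-05 to 0.934) and without Control 1, 4-NQO 1 and 4-NQO 3 (adjusted p = 0.000381, 0.000224 and 0.0222), while it pointed down without Control 2 and 4-NQO 2 (adjusted p = 0.934 and 0.812). The tumour-associated list passed without Control 2 (adjusted p = 0.00106, range 0.00106 to 0.941) and the inflammatory list without Control 1 (adjusted p = 0.000743, range 0.000743 to 0.82). Ccnd3, at 151 ± 32.4 and 414 ± 63.3 CPM (1.46 ± 0.17, adjusted p = 0.129), missed the threshold. It passed in 5 of 19 alternatives (adjusted p from 1.74e-12 to 0.903), and it was called in the macrophage-like clusters 1, 6 and 8 fitted alone. In all, 1 of 11761 genes was called and 394 had an unadjusted p under 0.05, where chance gives 588. DESeq2 called 4. The interferon list turned downward without Control 1 (adjusted p = 0.835) and without 4-NQO 1 (adjusted p = 0.329) and missed the threshold with the technical batch as a term (adjusted p = 0.738), in a range of 0.000114 to 0.907 over 11 alternatives. Dissociation stress missed it without Control 2 (adjusted p = 0.24) and hypoxia and glycolysis without Control 3 (adjusted p = 0.161), in ranges of 5.1e-06 to 0.763 and 4.63e-05 to 0.763.

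Neutrophil-like cells shared the lower hypoxia and glycolysis list: 19 of 19 members were lower, with a median of -0.37. The call was lost at an adjusted p = 0.422 with an estimated correlation. Egln3, an oxygen-sensing prolyl hydroxylase induced by HIF, was at 654 ± 84.7 CPM in controls and 447 ± 20.1 after 4-NQO (-0.55 ± 0.15), and Bnip3 at 334 ± 38.6 and 235 ± 15.4 CPM. MHC class II presentation fell with 6 of 7 members lower (median -0.58), lost at an adjusted p = 0.624 with an estimated correlation, among them H2-Ab1 at 63.6 ± 3.43 and 37.9 ± 5.79 CPM, 1.3% of its level in dendritic-like cells. The interferon response rose with 19 of 22 members higher (median 0.20), lost at an adjusted p = 0.68 with an estimated correlation, among them the GTPase gene Igtp at 123 ± 19.1 and 169 ± 16.0 CPM. Besides Ccnd3, Fkbp5 and Smyd3, Sla, an adaptor that dampens receptor signalling, rose from 113 ± 12.03 to 213 ± 6.82 CPM (0.91 ± 0.14, adjusted p = 0.0387, separated).

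The adjusted p was 7.2e-12 for hypoxia and glycolysis, 3.51e-08 for MHC class II presentation and 0.000142 for the interferon response at the preset correlation, and with an estimated correlation none passed. Over all genes 0 members of the 3 lists were called, and adjusted over the list alone 7, 4 and 0. The activated neutrophil list did not pass (10 of 15 members lower, adjusted p = 0.178), with Hilpda, a HIF-induced inhibitor of lipolysis, at 428 ± 72.5 and 236 ± 62.9 CPM. Of 9657 genes 4 were called, and 27 without Control 3. The interferon list missed the threshold without Control 3 (adjusted p = 0.067) and without 4-NQO 1 (adjusted p = 0.203), in a range of 3.43e-09 to 0.763. Sla lost its call without Control 1, Control 2 and 4-NQO 1, 2 and 3 (adjusted p = 0.255, 0.126, 0.304, 0.262 and 0.343) and in 7 of 18 alternatives altogether, in a range of 0.000247 to 1.

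T cells were compared for cytotoxic, exhausted, regulatory and type 17 programmes. Cluster 14, with Cd8a and Gzma among its most specific genes, scored highest for T markers but stayed unnamed. It was not part of T-like cells, and the lists written for T cells were not run in it. In T-like cells type 17 and gamma-delta T cell genes fell, with 9 of 9 members lower (median -1.01), a call lost at an adjusted p = 0.422 with an estimated correlation. Proliferation rose with 27 of 28 members higher (median 0.49), cytotoxic T cell genes with 9 of 10 higher (median 0.54) and T-cell exhaustion genes with 9 of 11 higher (median 0.30). These calls were lost at an adjusted p = 0.624 with an estimated correlation. Cluster 30, a T-like cluster with the histone gene Hist1h2ap among its most specific genes, made up 2.6 ± 0.9% of T-like cells in controls and 4.2 ± 0.9% after 4-NQO (n = 3 each, exact p = 0.1), and its part in the proliferation list was not tested. The cytokine gene Il17a was at 39.3 ± 27.5 CPM in controls and 1.55 ± 2.69 after 4-NQO (-4.40 ± 1.16, with -9.91, without 4-NQO 2, to -3.70 over 18 alternatives). The mitotic spindle gene Tpx2 was at 22.1 ± 2.89 and 37.2 ± 5.995 CPM (0.75 ± 0.17), the checkpoint receptor gene Pdcd1 at 71.0 ± 14.04 and 123 ± 6.32 CPM (0.80 ± 0.14). The perforin gene Prf1 was at 30.2 ± 3.62 and 46.7 ± 15.8 CPM, 4.8% of its level in NK-like cells. Dissociation stress genes fell with 13 of 19 members lower (median -0.32), lost at an adjusted p = 0.496 with an estimated correlation, Ier2 among them at 161 ± 6.60 and 121 ± 5.26 CPM.

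The adjusted p was 1.59e-14 for the type 17, 4.45e-16 for the proliferation, 6.15e-06 for the cytotoxic, 5.5e-05 for the exhaustion and 8.12e-06 for the dissociation stress list at the preset correlation, and with an estimated correlation none passed. Adjusted over the list alone, 6 proliferation, 6 dissociation stress and 1 exhaustion member were called, and over all genes 0. Regulatory T cell genes did not pass (adjusted p = 0.965; 5 of 9 members lower, while the test pointed up), with Foxp3 at 93.8 ± 18.6 and 85.9 ± 13.9 CPM. Of 10850 genes 4 were called (DESeq2 11). Beside Smyd3, Fkbp5 and Ccnd3 this was Dthd1, a death-domain gene below the level the naming rule asks for and named after its values were seen, at 1.67 ± 0.40 and 16.0 ± 2.38 CPM (3.22 ± 0.32, adjusted p = 0.00144, separated). Without Control 1, 4-NQO 1 and 4-NQO 2 the calls of Fkbp5 (adjusted p = 0.065, 0.0576 and 0.0543, range over 18 alternatives 1.73e-15 to 0.324) and Ccnd3 (adjusted p = 0.0869, 0.315 and 0.315, range 7.8e-09 to 1) were lost. That of Ccnd3 was also lost without Control 2 (0.05) and 4-NQO 3 (0.097), and the number called was 2 without 4-NQO 1 or 4-NQO 2 and 8 without Control 2. The cytotoxic list missed the threshold without 4-NQO 1 (adjusted p = 0.0669) and the exhaustion list without Control 3 (adjusted p = 0.08), in ranges of 1.83e-10 to 0.763 and 1.86e-13 to 0.763.

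In cluster 14, the lymphoid cluster with Cd8a and Gzma, Smyd3 fell from 1761 ± 117 to 606 ± 108 CPM (-1.54 ± 0.15, adjusted p = 8.54e-05), and Nrp1, a semaphorin and VEGF co-receptor, rose from 175 ± 24.5 to 358 ± 50.1 CPM (1.04 ± 0.15, adjusted p = 0.00831). Csf1, the macrophage growth factor, rose from 122 ± 11.6 to 257 ± 43.2 CPM (1.07 ± 0.16, adjusted p = 0.00831). It was named after its values were seen, since its level was 17.4% of that in neutrophil-like cells. All 3 were separated. Chemokines and cytokines rose as a list with 5 of 5 members higher (adjusted p = 1.38e-06), 1 of them called over all genes and 2 adjusted over the list alone. The interferon response rose with 15 of 17 higher (adjusted p = 2.26e-05), and both were lost at an adjusted p = 0.624 with an estimated correlation. Without Control 3 the number of genes called in cluster 14 was 5 in place of 3, and DESeq2 called 6 of 7756. Nrp1 lost its call without Control 1, Control 2 and 4-NQO 2 (adjusted p = 0.119, 0.0687 and 0.0762, range 5.82e-07 to 1). Csf1 lost it without Control 1, Control 2, 4-NQO 1 and 4-NQO 3 (adjusted p = 0.119, 0.0687, 0.0719 and 0.0536, range 7.04e-07 to 1).

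The smaller classes were compared in the same way. In B-like cells, with 2 control and 3 4-NQO libraries, 6 of 6354 genes rose (DESeq2 13). Fkbp5 went from 29.8 ± 2.27 to 180.1 ± 37.2 CPM (2.60 ± 0.28, adjusted p = 0.000757), Prkar2b, a regulatory subunit of protein kinase A, from 8.79 ± 3.43 to 81.2 ± 36.1 CPM (3.31 ± 0.47, adjusted p = 0.0107). The others were Pde8a, Fcrl5, Plscr1 and Ptpn22, the last named after its values were seen, with adjusted p from 0.0234 to 0.049 and no overlap of groups. Without Control 3, which leaves a single control assumed to vary like the other libraries, 88 genes were called in B-like cells, without 4-NQO 1 it was 2 and without 4-NQO 2 it was 1. Fkbp5 kept its call in each of 17 alternatives. Prkar2b lost it without Control 1, 4-NQO 1 and 4-NQO 2 (adjusted p = 0.0818, 0.0707 and 0.0637, range 6.01e-10 to 0.0818). The others lost it without some of Control 1 and 4-NQO 1, 2 and 3 (adjusted p between 0.0662 and 0.342, over their alternatives from 3.35e-06 to 0.597). Proliferation rose in B-like cells (7 of 8 members higher, median 1.22, adjusted p = 1.38e-06), lost at an adjusted p = 0.624 with an estimated correlation.

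The name lymphatic endothelial-like, given to 196 cells, depended on the resolution. At resolution 2 a cluster of 62 cells took this name, with too few cells per library for a test. Another of 133 cells, with a median of 967 UMIs and Fabp4 and Igfbp3 among its most specific genes, was named blood endothelial-like. In each library both clusters together came close to the number of cells in the class. In the lymphatic endothelial-like class named at resolution 1, 3 of 4105 genes were called. Sncaip, which encodes a synuclein-interacting protein, rose (1.92 ± 0.34, adjusted p = 0.0466, 48.9 ± 11.8 to 198 ± 29.6 CPM). The matricellular genes Thbs4 (-3.71 ± 0.48, adjusted p = 0.00347) and Postn (-2.65 ± 0.40, adjusted p = 0.0119) fell, all 3 separated. Thbs4 and Postn lay at 14.8% and 4.7% of their fibroblast-like level and were named after their values were seen. The number called was 27 without Control 1, 16 without 4-NQO 2 and 1 without Control 2 or Control 3. There Sncaip (adjusted p = 0.202 and 0.143, range 0.00116 to 0.211) and Postn (adjusted p = 0.0822 and 0.0687, range 2.35e-08 to 0.107) lost their calls. Sncaip also lost it without 4-NQO 1 and 4-NQO 3 (0.134 and 0.202) and Postn without 4-NQO 3 (0.107). Thbs4 lost its call in 1 of 14 alternatives (adjusted p from 6.26e-11 to 0.052), with a log2 fold change from -4.73 to -3.26. In blood endothelial-like cells the neutrophil genes S100a9 (-3.90 ± 0.45, adjusted p = 0.0143) and Il1b (-3.74 ± 0.44, adjusted p = 0.0163) fell in all 3 4-NQO libraries against 2 controls, at 0.5% and 0.7% of their neutrophil-like level and so outside the naming rule. These were 2 of 7933 genes tested, with 0 called without 4-NQO 2 or 4-NQO 3, 8 without Control 1 and 5 without Control 3. Neither S100a9 nor Il1b passed without Control 3 (adjusted p = 0.119 and 0.08), 4-NQO 2 (0.0683 for both) or 4-NQO 3 (0.0546 for both), in ranges of 8.15e-17 to 0.119 and 9.96e-21 to 0.08. Il1b also missed the threshold without 4-NQO 1 (0.0537). Angiogenic endothelium genes (13 of 17 lower, adjusted p = 0.0701) and activated endothelium genes (5 of 9 lower, adjusted p = 0.695) did not pass. The angiogenic list passed as lower without Control 3, 4-NQO 2 and 4-NQO 3 (adjusted p = 0.0355, 0.000672 and 0.00573) and pointed up without 4-NQO 1 (adjusted p = 0.768), in a range of 0.000672 to 0.895.

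With edgeR 0 genes were called in dendritic-like (272 of 9646 at an unadjusted p under 0.05, DESeq2 1), NK-like (256 of 5554, DESeq2 1) and the unnamed clusters 20 (462 of 7650, DESeq2 15), 24 (106 of 2537, DESeq2 1) and 25 (12 of 1484, DESeq2 0). At that unadjusted p chance gives 482, 278, 382, 127 and 74. In dendritic-like cells the interferon response fell, with 21 of 23 members lower and a median of -0.36 (adjusted p = 2.64e-07), lost at an adjusted p = 0.624 with an estimated correlation. It missed the threshold without Control 3 (adjusted p = 0.357, range 1.77e-18 to 0.763). The interferon-induced antiviral gene Bst2 was at 198 ± 8.52 CPM in controls and 162 ± 2.05 after 4-NQO in these cells. Cluster 20, with Krt13, Psca and Sprr1a among its most specific genes, had the interferon response (18 of 20 members, adjusted p = 0.000225), MHC class I (13 of 13, adjusted p = 0.000234) and MHC class II lists (5 of 5, adjusted p = 0.000165) higher, lost at an adjusted p = 0.68, adjusted p = 0.632 and adjusted p = 0.624 with an estimated correlation. The first missed the threshold without Control 3 (0.216) and 4-NQO 2 (0.136), the second without 4-NQO 2 (0.106) and the third without Control 1 (0.061), in ranges of 9.21e-13, 1.72e-06 and 2.11e-05 to 0.763. In all cells summed, where a change in composition enters, 0 of 18343 genes were called with edgeR and DESeq2 called 114. With edgeR 1346 had an unadjusted p under 0.05, where chance gives 917, and 13.5% of genes were separated against 10% by chance.

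Of the 133 pairs of a list and a class, 44 passed with camera at the preset correlation, 61 with the technical batch as a term, 0 with an estimated correlation and 0 with fry, a rotation test that asks whether the genes of a list move one way. For the pairs named here that passed, the highest adjusted p over the alternatives lay between 0.289 and 0.927. Whether a list differed more in one class than in another was not tested.

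**Figure D4:**
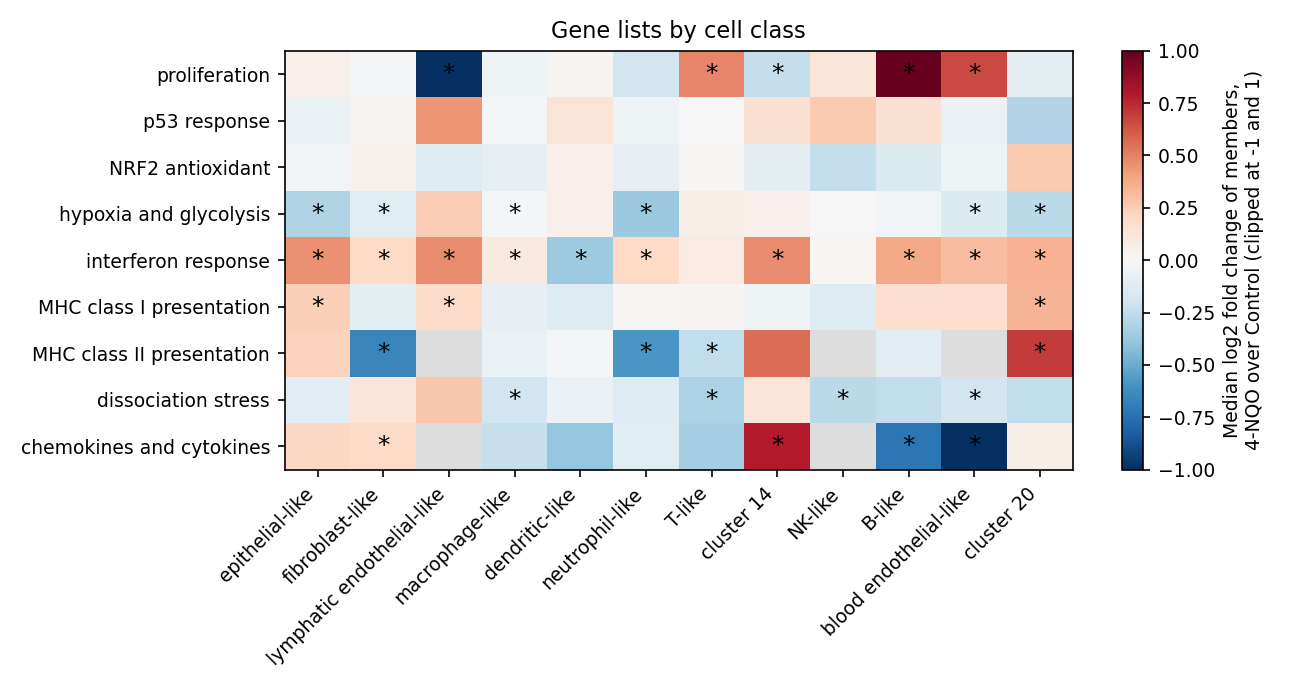
Median log2 fold change (4-NQO over Control) of the members of 9 gene lists in 12 cell classes, with asterisks where camera at the preset correlation passed after adjustment over 133 pairs and grey where fewer than 5 members were tested. The interferon response was higher in epithelial-like cells (0.46) and lower in dendritic-like cells (-0.36).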

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

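The alternatives chosen only after the results were seen were the removal of the highest doublet scores, clusters of shallow cells left out, each cluster fitted alone and the technical batch as a term. Of 1270 values of a named gene under an alternative other than leaving out a library, 1187 kept their direction and side of the threshold, 53 passed only there and 30 passed only as reported. On leaving out a library it was 578 of 643, with 6 passing only there, 55 no longer passing and 4 turning direction. For the pairs of a list and a class that are named, 158 of 230 were kept, with 63 passing only as reported, 7 passing only there and 2 turning direction. On leaving out a library it was 200 of 269, with 23, 18 and 28. Ccnd3, Smyd3 and Fkbp5 in neutrophil-like, Smyd3 and Dthd1 in T-like, Fkbp5 in B-like cells and Smyd3 in cluster 14 kept their calls under every alternative run for them. Scaling by median of ratios in edgeR left every count of genes within 1.5 times the count reported and called 44 list pairs. Recovery differed between classes. With a planted 2-fold change, edgeR recovered 14.8% of genes in lymphatic endothelial-like, 3.4% in cluster 24 and 0% in cluster 25. The cause of that and of the differences that follow was not tested, except that the no-filter setting tests more genes and that leaving out a library or cluster leaves fewer counts.

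With DESeq2 the number of genes called was 13 in B-like, 1 in NK-like, 11 in T-like, 8 in blood endothelial-like, 6 in epithelial-like, 6 in fibroblast-like, 1 in dendritic-like, 11 in lymphatic endothelial-like and 4 in macrophage-like cells, 6 in cluster 14, 15 in cluster 20, 1 in cluster 24 and 114 in all cells summed. With no filter on low counts it was 57 in B-like, 14 in NK-like, 92 in T-like, 88 in blood endothelial-like, 26 in dendritic-like, 3 in fibroblast-like, 116 in lymphatic endothelial-like, 14 in macrophage-like and 29 in neutrophil-like cells, and 61, 95, 45 and 3 in clusters 14, 20, 24 and 25. Against a fold of 1.5 it was 2 in B-like, 2 in T-like and 0 in macrophage-like cells and 1 in cluster 14. At resolution 2 it was 0 in blood endothelial-like and macrophage-like cells. At most 10% mitochondrial UMIs gave 2 in B-like and 0 in blood endothelial-like cells. With doublets kept it was 1 in NK-like cells and 7 in cluster 14, and without the highest doublet scores 14 in B-like, 4 in NK-like and 0 in blood endothelial-like cells. Sums thinned to the smallest gave 3 in NK-like, 7 in blood endothelial-like, 0 in lymphatic endothelial-like and 2 in macrophage-like cells. With only genes not far higher in another class it was 0 in blood endothelial-like, 0 in lymphatic endothelial-like and 2 in macrophage-like cells. Without shallow clusters it was 0 in macrophage-like cells, and with each cluster fitted alone the distinct genes numbered 1 in dendritic-like, 3 in epithelial-like, 3 in fibroblast-like and 8 in macrophage-like cells. With the technical batch as a term it was 5 in NK-like, 7 in T-like and 7 in blood endothelial-like cells, 8 in cluster 14, 1 in cluster 24 and 1 in all cells summed. Of the list pairs, 0 passed with camera at an estimated correlation and 0 with fry.

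The groups share replicate numbers, which nothing in the labels says pair the mice. Controls and 4-NQO libraries of one number correlated at -0.131, 0.385 and 0.17 after centring each group, so not each above 0.1, and Control 3 went best with 4-NQO 1 (0.38). With a replicate block the number of genes called was 12 in B-like, 4 in NK-like, 15 in T-like, 4 in blood endothelial-like, 1 in dendritic-like, 1 in lymphatic endothelial-like and 2 in macrophage-like cells, 15 in cluster 14 and 1 in cluster 20. With it the wound and stress keratinocyte list in epithelial-like (adjusted p = 0.0446) and the angiogenic endothelium list in blood endothelial-like cells (adjusted p = 0.00121) passed, and the interferon list in macrophage-like cells did not (adjusted p = 0.0649). Il17a in T-like cells also passed with it (adjusted p = 0.0288).

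Leaving out each library in turn gave 1 to 88 genes in B-like cells (88 without Control 3, 2 without 4-NQO 1, 1 without 4-NQO 2), 0 to 2 in NK-like (1 without Control 2, 2 without Control 3), 2 to 8 in T-like (8 without Control 2, 2 without 4-NQO 1 or 4-NQO 2), 0 to 8 in blood endothelial-like (8 without Control 1, 5 without Control 3, 0 without 4-NQO 2 or 4-NQO 3), 1 to 27 in lymphatic endothelial-like (27 without Control 1, 16 without 4-NQO 2, 1 without Control 2 or Control 3), 3 to 27 in neutrophil-like (27 without Control 3), 0 to 1 in dendritic-like (1 without 4-NQO 3) and 0 to 1 in macrophage-like cells (1 only without 4-NQO 3). It gave 2 to 5 in cluster 14 (5 without Control 3), 0 to 2 in cluster 20 (2 without Control 2, 1 without 4-NQO 2) and 0 to 1 in cluster 24 (1 without Control 2 or 4-NQO 1). Where this left 1 control, in B-like and blood endothelial-like cells, that library was assumed to vary like the others.

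Some lists that passed turned direction. The interferon list in macrophage-like cells did so without 4-NQO 1 (adjusted p = 0.329) and without Control 1 (adjusted p = 0.835), in a range of 0.000114 to 0.835. The hypoxia and glycolysis list in fibroblast-like cells did so with the technical batch as a term (adjusted p = 0.666), without Control 1 (adjusted p = 0.584) and without 4-NQO 1 (adjusted p = 0.764), in a range of 1.71e-08 to 0.764 on leaving out a library.

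Among lists that did not pass as reported, directions turned as follows, with adjusted p and then its range on leaving out a library. In epithelial-like cells proliferation turned without Control 3 (0.0348) and 4-NQO 2 (0.0108), range 0.00259 to 0.061. Keratinocyte differentiation turned there without Control 3 (0.527) and 4-NQO 2 (0.293), range 0.126 to 0.548, and the p53 response without 4-NQO 2 (0.987), range 0.404 to 0.987. The NRF2 antioxidant list turned with the technical batch as a term (0.4) and without Control 1 (0.55), 4-NQO 1 (0.869) and 4-NQO 3 (0.632), range 0.322 to 0.869. In fibroblast-like cells the steady-state list turned without Control 3 (0.252) and 4-NQO 3 (0.583), range 0.0106 to 0.583. The inflammatory list turned without Control 1 (0.835), Control 3 (0.687) and 4-NQO 1 (0.638), range 0.147 to 0.835, and the collagen list without Control 1 (0.903) and 4-NQO 2 (0.987), range 0.379 to 0.987. In macrophage-like cells the tumour-associated list turned without Control 1 (0.375) and 4-NQO 2 (0.941), range 0.00106 to 0.941, and the tissue-resident list without Control 2 (0.934) and 4-NQO 2 (0.812), range 0.000224 to 0.934. The regulatory list in T-like cells turned without Control 1 (0.132) and 4-NQO 2 (0.763), range 0.132 to 0.94. In blood endothelial-like cells the angiogenic list turned without 4-NQO 1 (0.768), range 0.000672 to 0.768, and the activated list without Control 3 (0.445) and 4-NQO 2 (0.759), range 0.102 to 0.964.

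Single genes and shares turned too. The log2 fold change of Krt15 in epithelial-like cells, -0.17 as reported, was 0.20 without 4-NQO 2 and 0.17 without Control 3 (-0.45 to 0.20 on leaving out a library). That of Gapdh there, 0.06, was -0.05 without Control 2 (-0.05 to 0.13). That of Foxp3 in T-like cells, -0.13, was 0.04 without Control 3 (-0.25 to 0.04). The 4-NQO minus Control difference in share, in percentage points, of cluster 25, -0.02 as reported, was 0.39 with all deposited barcodes and 0.01 without the highest doublet scores, and that of lymphatic endothelial-like cells, 0.07, was -0.13 without them. On leaving out a library these differences ranged from -0.43 to 0.77 for cluster 14, from -0.37 to 0.38 for cluster 25, from -0.08 to 0.19 for lymphatic endothelial-like, from -1.32 to 9.51 for neutrophil-like and from -1.76 to 0.60 for B-like cells. They turned without 4-NQO 3 or Control 1 for neutrophil-like cells (-0.84 and -1.32) and lymphatic endothelial-like cells (-0.01 and -0.08), without Control 1 for B-like cells (0.60), without 4-NQO 1, 4-NQO 2, Control 2 or Control 3 for cluster 14 (-0.22, -0.06, -0.05 and -0.43), and without 4-NQO 1, 4-NQO 3 or Control 2 for cluster 25 (0.01, 0.05 and 0.38).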

Other observations

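The counts of other splits of the libraries for genes, the test for an exchange of libraries, the technical batch and the fits of single clusters were chosen only after the results were seen. The other tests below were written before the values they measure.

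Vascular and minor clusters showed further list changes. In blood endothelial-like cells proliferation genes were higher (19 of 25 members, median 0.66, adjusted p = 6.59e-11, and adjusted p = 0.624 with an estimated correlation), among them the kinetochore gene Cenpf at 8.35 ± 4.84 CPM in 2 controls and 59.5 ± 17.99 in 3 4-NQO libraries. The log2 fold change of Cenpf ranged from 0.06, at resolution 2, to 3.57 over 17 alternatives. Without Control 1 the list missed the threshold (adjusted p = 0.102, range 1.19e-16 to 0.763). Chemokines and cytokines were lower there (5 of 6 members, median -3.33, adjusted p = 1.49e-29, and adjusted p = 0.197 with an estimated correlation, range 5.72e-42 to 0.289), a list that holds Il1b, which lay at 0.7% of its neutrophil-like level. In lymphatic endothelial-like cells proliferation genes were lower (7 of 7 members, median -1.98, adjusted p = 4.44e-06, and adjusted p = 0.624 with an estimated correlation, range 1.3e-25 to 0.763), with Mki67 at 269 ± 255 and 30.8 ± 32.7 CPM. The log2 fold change of Mki67 ranged from -4.6 to -2.66 over 12 alternatives, and with edgeR it passed only without Control 1 (adjusted p = 0.0132). The difference between both endothelial classes was not tested. At resolution 2 the cells of the lymphatic endothelial-like class were named blood endothelial-like in larger part, so the 2 classes are not cleanly apart.

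Within T-like cells, cluster 12 made up 35.9 ± 6.3% of the class in controls (43.1, 31.8 and 32.7% in Control 1 to 3) and 27.1 ± 1.1% after 4-NQO (n = 3 each, two-sided exact p = 0.1, the smallest that 3 against 3 allow). Cxcl5, a neutrophil chemoattractant, was at 703 ± 276 CPM in controls and 1956 ± 810 after 4-NQO in cluster 20 (1.47 ± 0.41, adjusted p = 0.619, separated). Junb, an immediate early gene, was at 1251 ± 292 and 849 ± 216 CPM in NK-like cells (adjusted p = 0.916, separated).

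Fkbp5 and Ccnd3 were higher and Smyd3 lower in most of 9 classes with 6 libraries, a pattern chosen after the values were seen. By CPM without TMM scaling Smyd3 was separated in 9 of 9 classes and Fkbp5, Ccnd3 and Hspa8 in 7, while with TMM scaling Smyd3 overlapped in dendritic-like cells (110.9 CPM in Control 1 and 111.7 in 4-NQO 3). With the measured CPM multiplied by random noise, this count found 200 of 200 genes with a planted 4-fold change and 1 of 7074 others. The noise was independent between classes and the labels were kept, while the real classes share the same mice. It therefore does not measure how often such a count arises without a group difference.

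For Fkbp5, Ccnd3 and Smyd3 across classes, a difference in the time of day of sampling stays open. In all cells summed, an index of 7 clock output genes minus 3 core clock genes differed by -0.15 ± 0.15 (SE) on the log2 scale. This met the bound set in advance, where the difference and 2 SE together had to stay below 0.5. With 3 libraries against 3, 2 SE understate the uncertainty, and the index can take the same value at different times. It therefore cannot exclude such a difference. Glucocorticoid exposure may contribute and stays open, since the 17 further glucocorticoid-induced genes pointed upward as a list in 9 of 9 classes but passed as a list in 2 of them (fibroblast-like p = 3.9e-05 and lymphatic endothelial-like p = 0.000976 with camera, and p = 0.0704 and p = 0.0353 with an estimated correlation). A linked stretch of the genome that differs between the groups' mice also stays open, since 2 of the 4 genes lie within a 20 Mb window of chromosome 17, which 10% of 10000 random draws equalled. An effect of 4-NQO or of the lesions on these genes is the explanation the design names. It cannot be told apart from the others because nothing recorded the sampling time, hormone status or origin of each mouse.

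A split of the libraries across the labels, Control 1, Control 2 and 4-NQO 2 against the rest, called 337 genes in epithelial-like cells and points to a structure of the samples. It coincides with the technical batch (0.0856 to 0.096% against 0.1167 to 0.1432% of UMIs on AY036118 and Lars2), which was defined after that split had been seen. Cell composition follows the split as well, with 14.7 to 20.6% against 31.3 to 36.3% neutrophil-like, 12.8 to 14.5% against 7.63 to 8.88% T-like and 26.5 to 31.5% against 19.8 to 24.1% macrophage-like cells, so whether it is technical was not settled. Each batch holds 2 mice of one group and 1 of the other, too few for values within a batch. With the batch as a term 0 genes were called in epithelial-like, 1 in macrophage-like, 4 in neutrophil-like, 7 in T-like and 5 in NK-like cells, 8 in cluster 14, 0 in cluster 20, 1 in all cells summed, and 61 list pairs.

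For that split, free RNA from neutrophils is argued against as the source of most of the 254 epithelial genes higher in the second set. Of these, 23.2% were at a higher level in neutrophil-like than in epithelial-like cells, against 32.2% of all genes tested. Such a share cannot exclude free RNA for some of the genes. That the mix of epithelial clusters differs between the libraries may account for part of it and stays open, since the 3 clusters fitted alone called 0, 34 and 2 genes, between the bounds set in advance. That 1 control and 1 OSCC library were exchanged stays open too, since the labels separated 4 genes in one direction in at least 7 of 9 classes, the highest of the other splits 24 and the remaining 8 splits 0 each. The 4 thus lay above the median of the other splits but not above each of them, and no biological explanation was tested for this pattern.

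That no gene was called in epithelial-like cells could reflect a mixture of epithelial clusters that hides changes within one, and this stays open. Fitted alone, clusters 2, 3 and 10 called 1 gene each, Cst6 lower, Smyd3 lower and Ccl2 higher. This met the bound set in advance against such a mixture. A cluster alone holds fewer counts than the class, so few calls cannot exclude hidden changes. Whether the technical split of the libraries widens the spread and hides changes stays open. With the batch as a term 0 genes were called in these cells, but the term also costs power with so few libraries. The split itself called 337 genes there. In simulated data edgeR recovered 60.6% of genes with a planted 2-fold change and 9% with a planted 1.5-fold change. Those data held 200 changed genes, counts independent between genes and no split across the labels, so real recovery may be lower. In the real fit of fibroblast-like cells Zbtb16 missed the threshold at a log2 fold change of 3.30 (edgeR adjusted p = 0.143). Changes of 2-fold as well as smaller ones, shared by the mice, therefore remain possible. The design names exposure to 4-NQO as the biological explanation to set beside these, and no test here tells a small effect of it from none.

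The 6 libraries make 10 splits into equal groups, too few for a share under 0.05. The labels called 4 genes in neutrophil-like cells and the highest other split 52, 4 and 26 in T-like, 1 and 31 in macrophage-like cells and 3 and 18 in cluster 14, with as many in 2 of the 10 splits each. They called 3 in lymphatic endothelial-like cells, the highest other split 1, with as many in 1 split, the labelled one. Where the labels called 0, as many in 10 of 10 splits was fixed in advance and says nothing. The highest other split there called 337 in epithelial-like, 1 in fibroblast-like, 2 in dendritic-like and 35 in NK-like cells. It called 19, 1 and 6 in clusters 20, 24 and 25, and 18 in all cells summed. Over the list pairs with 6 libraries the labels called 35 and the highest other split 45, with as many in 6 of the 10 splits.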
